A study of Homo sapiens with 6 samples.

How the data were processed

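Whether polyadenylated or total RNA was sequenced is not given in the sources used here. RNA was taken from THP-1 cells after PMA with Vezol reagent, per the labels' protocols, and libraries were sequenced on a DNBSEQ-T7 instrument by a service provider. Reads were trimmed with fastp version 0.23.0 and referred to the human genome GRCh38, per the submitters' processing notes. The aligner, the counting program, the annotation release and the use of strand are not given in the sources used here. The deposited table holds whole-number counts per gene, not normalized, for 61267 genes and 6 libraries, with exon coordinates and exon length for each gene. No row lacked a gene name. Coordinates are given as the deposited table gives them, on GRCh38. Biotypes came from matching the gene symbols to a RefSeq gene table, which matched 40163 genes, 19153 of them protein-coding.

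The 6 samples fell into 2 groups of 3 by their labels, NC and KD. Depth was 37628972 to 42970216 total counts per library. Each library was counted as a sample, as labelled. No pair within a group held identical counts or agreed within sampling noise (chi-square per degree of freedom 3.24 to 6.46), a spread that may be technical and that counting both reads of a pair also raises. Between 67.8% and 70.3% of the counts from 1 to 20 were even, against 50.2% to 51.4% of those over 1000, as when both reads of a pair are counted, so that small counts hold fewer independent fragments than their number. Some genes with common exons held identical counts in every library, so that reads overlapping several genes were counted for each of them in the authors' table.

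Changes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM normalization and the filterByExpr filter, which left 21905 genes. The threshold was a Benjamini-Hochberg adjusted p of 0.05, two-sided. Log2 fold changes are those of edgeR, and each standard error is the log2 fold change divided by the square root of the F statistic. CPM values, counts divided by the scaled library size, use TMM in the report, and library size alone for the genes of the leukocyte, HEK293-type and chromosome 9 lists. The common biological coefficient of variation was 0.0499. Fold bounds for genes with no count in KD set the group at 3 counts, and 95% intervals of count ratios are exact binomial ones. These cover counting error only and take each count as an independent fragment. Where both reads of a pair were counted, the intervals are too narrow and the bounds too high.

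A total of 38 gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for the 36 lists with at least 5 tested members, adjusted over those 36. Camera with an estimated correlation and fry stood beside it. Genes named in the text are METTL1 and WDR4, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, the 5 smallest p-values not yet named, and up to 4 examples per list with the smallest p, of which 3 were taken, except that 2 of these examples are not reported here. Genes outside this rule are said to be chosen after their values were seen, or come from lists written after the data were seen.

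The alternatives were DESeq2 size factors, library sizes alone, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, no robust estimation, a replicate block, leaving out each library, an adjusted p of 0.01 and a test against a fold of 1.5. Added after the data were seen were TMM over 58 tested genes that are restricted to leukocytes, counts divided by 2, and the removal of genes averaging fewer than 10 counts in KD. Lists for leukocyte-restricted genes and other cell types, and 15 gene families, were also written after the data were seen. On simulated counts for KD against NC, the edgeR steps recovered 74% of 50 genes changed 1.25-fold, 98% at 1.5-fold, and 100% at 2-fold and 4-fold, and called 7 unchanged genes among 21433. Camera called 10 of 10 raised lists and 0 of 30 unchanged ones. For the edgeR steps few genes were changed, as many up as down. All simulated counts used a single dispersion and genes drawn independently. In these data 76.5% of the tested genes passed, so the simulation does not show how the steps perform when most genes differ or when list genes vary together. Scripts also used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.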

Results

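RNA levels were measured by sequencing in THP-1 cells, a human monocytic leukemia line, that had been given phorbol ester (PMA) at 100 ng/ml for 48 h, a treatment after which these cells attach and take on macrophage features. The series title names METTL1, the enzyme that places 7-methylguanosine (m7G) in tRNA and other RNA, and acute inflammation. Of the 6 libraries, 3 were labelled NC and 3 were labelled KD, and the labels name no target for KD. Total counts per library ran from 37628972 to 42970216. A mean of 31546 ± 174 genes had a count in the NC libraries and 29363 ± 9.71 in the KD libraries (mean ± SD, n = 3 each). Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

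The first question was whether the labels were matched by the level of METTL1, with its cofactor WDR4 beside it. METTL1 (chromosome 12, 57768471 to 57772119, minus strand, GRCh38) stood at 14.8 ± 1.02 CPM in NC and 13.7 ± 0.605 CPM in KD (mean ± SD, n = 3 each, TMM-scaled CPM). The log2 fold change, KD over NC, was -0.11 with an SE of 0.076 and did not pass the test (edgeR adjusted p = 0.216). The NC libraries held 596, 653 and 642 counts of METTL1 and the KD libraries 567, 528 and 524. The direction of every difference given here is that of libraries labelled KD against libraries labelled NC. WDR4 (chromosome 21, 42843094 to 42879568, minus strand), the partner that METTL1 needs for its activity on tRNA, fell from 7.27 ± 0.317 to 4.77 ± 0.713 CPM, with a log2 fold change of -0.61 and an SE of 0.117 (edgeR adjusted p = 5.04e-05). With library sizes alone the METTL1 log2 fold change was -0.29 (adjusted p = 0.00249), and without genes that averaged fewer than 10 counts in the KD libraries it was -0.18 (adjusted p = 0.0382). Of the 1947 exon bases of METTL1, 107 also lie in exons of CYP27B1 and 114 in exons of EEF1AKMT3 on the other strand. Reads there cannot be assigned to one gene, since CYP27B1 lies on the same strand as METTL1 and since, for EEF1AKMT3, the use of strand is not given in the sources used here.

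**Figure D1:**
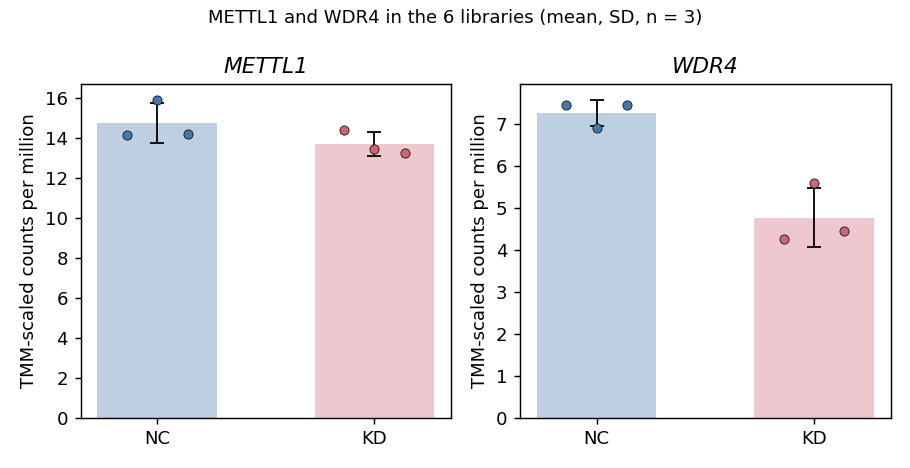
METTL1 (left) and WDR4 (right) in each library, as TMM-scaled CPM on axes that start at 0. Points are libraries, bars are group means and error bars are the SD (n = 3). METTL1 averaged 14.8 in NC and 13.7 in KD, and WDR4 averaged 7.27 in NC and 4.77 in KD.

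The second comparison asked which genes differed between the KD and the NC libraries. The largest rises in KD included mediators of inflammation. IL23A, a subunit of interleukin 23, rose from 20.6 ± 0.459 to 193 ± 13.8 CPM. The hyaluronan-degrading factor CEMIP rose from 28.9 ± 0.531 to 187 ± 2.54 CPM. The cytokines TSLP (2.86 ± 0.130), CSF2 (2.76 ± 0.183) and IL1A (2.66 ± 0.111) rose too, where the brackets hold the log2 fold change, KD over NC, ± its SE. The remaining genes among the 10 largest rises were the calcium-binding protein CALB2 (3.59 ± 0.124), the glutamate transporter SLC1A2 (3.15 ± 0.20), the transcription factor DMRT2 (2.81 ± 0.160), the lectin FCN1 (2.72 ± 0.166) and the synaptic protein RIMS1 (2.67 ± 0.161). The largest falls were of genes that were abundant in NC and close to 0 in KD. The neurofilament gene NEFM stood at 1595 ± 198 CPM in NC and 0.390 ± 0.0282 CPM in KD, a 4106-fold difference (95% interval of the count ratio 3078 to 5609). No count in any KD library was found for the RNA-binding protein LIN28B (86.4 ± 3.41 CPM in NC, at least 3400-fold lower in KD), ID4 (62.7 CPM, at least 2470-fold), GALNT13 (31.3 CPM, at least 1229-fold) or POU3F3 (26.4 CPM, at least 1041-fold). The same held for MAGED4B (18.8 CPM, at least 742-fold), ITPRIPL1 (11.6 CPM, at least 455-fold), ZCCHC12 (10.4 CPM, at least 408-fold), FGFR2 (8.93 CPM, at least 351-fold) and PAX3 (8.85 CPM, at least 348-fold). Reads of MAGED4B can be shared with its near-identical copy MAGED4. The bounds set the KD group at 3 counts, and intervals and bounds cover counting error only. Both take counts as independent, so counting both reads of a pair would make the interval too narrow and the bounds too high. The 5 smallest p-values not yet named belonged to BEX2 (-8.87 ± 0.086), the insulin receptor substrate IRS4 (-9.90 ± 0.097), the desmosome genes DSP (-6.83 ± 0.069) and DSG2 (-7.24 ± 0.074) and the non-muscle myosin MYH10 (-6.12 ± 0.066). CDKN2A, chosen after its values were seen, is known to be lacking in THP-1 cells. It was at 38.6 ± 1.65 CPM in NC, scaled by library size alone. Falls here and in the lists below may thus come from RNA of other cells in NC, and rises from dilution of THP-1 RNA there.

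Of 21905 tested genes, 16758 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 7934 of them higher and 8824 lower in KD. A change of at least 2-fold was found for 7773 genes, 2755 higher and 5018 lower. The CPM values of the groups did not overlap for 78% of the tested genes, where chance gives 10%. The split depends on the scaling: with library sizes alone 6212 genes were higher and 10369 lower, so that 37.5% of the calls were higher in place of 47.3%. The median log2 fold change of all genes was then -0.23 in place of -0.05. A scaling that sets 58 leukocyte-restricted genes level was chosen after the data were seen and is called the leukocyte scale here. On it 590 genes were higher and 18636 lower (3.1% of the calls higher) and the median was -1.32. Most genes are thus lower on this scale, so lower members or a change of sign there do not by themselves set a list apart. METTL1 was at -1.38 on the leukocyte scale (adjusted p = 8.87e-15), below 0 by about as much as the median gene. On the scale of all tested genes, 56 of those 58 genes were higher in KD. The 10 largest rises named above stayed higher in KD on the leukocyte scale, but by less. Their log2 fold changes there ran from 1.38 for IL1A to 2.31 for CALB2.

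**Figure D2:**
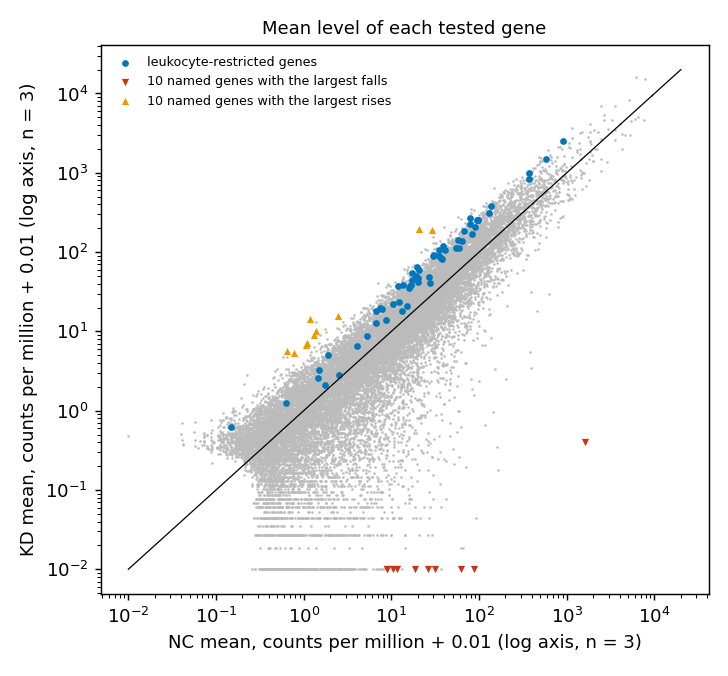
Mean level of each tested gene in the NC libraries (horizontal) and the KD libraries (vertical), as CPM plus 0.01 on log axes, n = 3 each, without X-inactivation and Y-linked genes. The line marks equal levels. The 58 leukocyte-restricted genes (blue) lie mostly above it, with a median log2 fold change of 1.27. Of the 10 named genes with the largest falls (red), 9 lie at a KD count of 0, with NEFM to their right at 1595 CPM in NC.

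Markers of cells other than macrophages went in both directions. The keratins KRT8 (-3.30 ± 0.065) and KRT18 (-4.36 ± 0.079) and the smooth muscle actin ACTA2 (-5.63 ± 0.288) fell. The epithelial and fibroblast list had 1 higher and 7 lower of 9 tested (camera adjusted p = 0.0303, adjusted p = 0.124 with an estimated correlation, and adjusted p = 0.0594 with library sizes alone). The 3 tested B cell and plasma cell genes were all lower, among them PAX5 (-0.95 ± 0.185) and CR2 (0.469 CPM in NC and 0 in KD). Among 7 T and NK cell genes 4 were higher and 1 lower (camera adjusted p = 0.178), with 2 higher and 3 lower on the leukocyte scale. Of these, GNLY (2.43 ± 0.134) and CD5 (1.98 ± 0.326) rose on both scales, while TRAC (1.45 ± 0.176) did not pass on the leukocyte scale. Of 3 erythroid and megakaryocytic genes 1 was higher and 1 lower, with 0 higher and 2 lower on the leukocyte scale. ITGA2B (-4.53 ± 0.411) fell, PPBP (1.22 ± 0.265) rose but was at -0.05 on the leukocyte scale, and EPOR did not pass. The EPOR log2 fold change was -0.21 with an SE of 0.252, and 0.081 without KD replicate 1.

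Genes of inflammation were mostly higher in the KD libraries on the scale of all genes. The pro-inflammatory cytokines had 15 higher and 2 lower of 19 tested (camera adjusted p = 2.73e-05, adjusted p = 0.0697 with an estimated correlation), with 11 higher and 4 lower on the leukocyte scale. Those with the smallest p were IL23A, TNFSF15 (2.04 ± 0.047) and CSF1 (1.61 ± 0.043). Chemokines had 13 higher and 5 lower of 19 tested (camera adjusted p = 0.00199, adjusted p = 0.235 with an estimated correlation), with 9 higher and 8 lower on the leukocyte scale. CXCL8, which attracts neutrophils, rose from 1159 ± 26.6 to 3683 ± 80.1 CPM, beside CCL1 (2.01 ± 0.043) and CXCL3 (1.61 ± 0.044). All 19 NF-kB feedback targets were higher (camera adjusted p = 1.59e-10, and adjusted p = 0.0336 with an estimated correlation), whereas 5 were higher and 6 lower on the leukocyte scale. The smallest p among them belonged to TNFAIP2 (1.70 ± 0.044), BCL2A1 (1.62 ± 0.042) and BIRC3 (1.52 ± 0.043). The inflammasome and pyroptosis list had 13 higher and 1 lower of 15 tested (camera adjusted p = 2.60e-04, adjusted p = 0.0541 with an estimated correlation), but 2 higher and 8 lower on the leukocyte scale. NLRP3, the inflammasome sensor, stood at 32.9 ± 2.03 CPM in NC and 90.7 ± 3.67 CPM in KD. P2RX7 (1.40 ± 0.043) and CASP4 (1.27 ± 0.047) were higher too, with CASP4 at -0.001 on the leukocyte scale. Toll-like receptors and adaptors had 13 higher and 1 lower of 16 tested (camera adjusted p = 1.80e-04, adjusted p = 0.0541 with an estimated correlation) and 1 higher and 9 lower on the leukocyte scale. TLR2 (1.52 ± 0.054) and TLR1 (1.37 ± 0.074) were higher, TLR1 without passing on the leukocyte scale, and IRAK3 (1.20 ± 0.051) was at -0.07 there. Type I interferon-stimulated genes had 20 higher and 9 lower of 32 tested, or 20 higher and 10 lower adjusted over the list alone, and all 32 were lower on the leukocyte scale. Their test (camera adjusted p = 0.0472, adjusted p = 0.125 with an estimated correlation) did not pass without NC replicate 3 (adjusted p = 0.0567) or with library sizes alone (adjusted p = 0.128). The antiviral gene RSAD2 (-0.80 ± 0.047) fell, while SAMD9L (1.18 ± 0.040) and IRF9 (1.07 ± 0.044) were higher on the scale of all genes only. For all lists fixed before the data were examined, the counts adjusted over the list alone were the same as those over all genes tested, except for the interferon list and oxidative phosphorylation. In the same NC libraries NEFM stood at 1595 CPM and KRT8 at 57.8 CPM.

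Genes of the macrophage state followed the same division between the scales. The PMA-induced differentiation list had 20 higher and 2 lower of 22 tested (camera adjusted p = 1.80e-08, adjusted p = 0.0697 with an estimated correlation) but 4 higher and 15 lower on the leukocyte scale. Fibronectin (FN1) rose from 88.1 ± 1.57 to 339 ± 6.88 CPM and APOE (1.69 ± 0.042) rose as well, on both scales, while the early growth response gene EGR1 (-2.32 ± 0.058) fell. Markers of classical (M1) activation had 12 higher and 0 lower of 14 tested (camera adjusted p = 9.74e-05, adjusted p = 0.0541 with an estimated correlation) and 2 higher and 8 lower on the leukocyte scale. INHBA (1.51 ± 0.041) and SOCS3 (1.51 ± 0.065) were higher, and GBP2 (1.13 ± 0.052) was at -0.15 on that scale. Markers of alternative (M2) activation had 12 higher and 1 lower of 13 tested (camera adjusted p = 1.65e-04, adjusted p = 0.0541 with an estimated correlation) and 1 higher and 7 lower on the leukocyte scale. Among them IL1RN (1.33 ± 0.042), MSR1 (1.23 ± 0.042) and TGM2 (1.15 ± 0.044) were higher on the scale of all genes, while on the leukocyte scale IL1RN did not pass, MSR1 was at -0.04 and TGM2 at -0.12. Immature myeloid granule genes had 5 higher and 0 lower of 9 tested (camera adjusted p = 0.171), against 0 higher and 9 lower on the leukocyte scale. With library sizes alone 3 were higher and 1 lower, and 3 were higher without NC replicate 1. CTSG (0.74 ± 0.112), LYZ (0.50 ± 0.072) and RNASE2 (0.57 ± 0.126) reversed between the scales. Fc receptors and complement had 8 higher and 2 lower of 15 tested (camera adjusted p = 0.0249, adjusted p = 0.166 with an estimated correlation) and 1 higher and 10 lower on the leukocyte scale. C5AR1 (1.22 ± 0.049), FCER1G (1.05 ± 0.042) and C3 (1.04 ± 0.040) were below 0 on that scale. FCER1G is itself among the 58 genes that set that scale, so its sign there only places it within that set. Lysosomal genes had 24 higher and 2 lower of 27 tested (camera adjusted p = 5.76e-08, adjusted p = 0.127 with an estimated correlation) and 0 higher and 27 lower on the leukocyte scale. CTSH (1.09 ± 0.044), MAN2B1 (1.07 ± 0.040) and PSAP (1.01 ± 0.041) changed sign between the scales. Matrix metalloproteinases and matrix genes had 18 higher and 3 lower of 22 tested (camera adjusted p = 4.24e-06, adjusted p = 0.0541 with an estimated correlation) and 7 higher and 10 lower on the leukocyte scale. The collagenase MMP1 rose from 604 ± 23.3 to 1945 ± 42.3 CPM and MMP8 (1.96 ± 0.043) rose with it. MHC class I presentation had 11 higher and 3 lower of 15 tested (camera adjusted p = 0.0224, adjusted p = 0.114 with an estimated correlation) and 0 higher and 14 lower on the leukocyte scale. HLA-C fell from 117 ± 2.18 to 6.70 ± 0.560 CPM and HLA-B (-1.92 ± 0.044) fell, but these genes are polymorphic and can share reads with their relatives, which leaves their levels uncertain. PSMB8 (1.19 ± 0.044) was higher on the scale of all genes only. MHC class II presentation had 3 higher and 5 lower of 10 tested and 0 higher and 9 lower on the leukocyte scale. Its median log2 fold change was -0.48 and its mean -1.08, while camera gave the direction up (camera adjusted p = 0.924). The invariant chain CD74 (1.18 ± 0.046) and HLA-DRB1 (0.80 ± 0.080) were higher on the scale of all genes only, and HLA-DMB (-3.56 ± 0.386) fell. DSP, a gene of epithelial junctions, was at 389 ± 24.1 CPM in NC and 3.42 ± 0.319 CPM in KD.

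S-phase and mitosis genes were lower in the KD libraries on each scale. Of the S-phase and DNA replication genes 26 of 27 were lower and 0 higher (camera adjusted p = 7.88e-12, and adjusted p = 0.0336 with an estimated correlation), and all 27 were lower on the leukocyte scale. The replication factor CDC45 fell from 134 ± 4.55 to 16.7 ± 1.69 CPM, with MCM7 (-2.02 ± 0.042) and MCM2 (-1.85 ± 0.043) of the replicative helicase. All 27 mitosis genes were lower (camera adjusted p = 1.32e-12, adjusted p = 0.0541 with an estimated correlation), among them BIRC5 (-2.76 ± 0.057), ASPM (-2.50 ± 0.048) and CENPE (-2.49 ± 0.046). Replication-dependent histones had 9 higher and 1 lower of 11 tested (camera adjusted p = 0.0118, adjusted p = 0.0975 with an estimated correlation) and 0 higher and 5 lower on the leukocyte scale. H2AC6 (1.14 ± 0.069), H2BC21 (1.13 ± 0.127) and H2BC12 (0.89 ± 0.088) were higher on the scale of all genes only. The p53 targets had 11 higher and 4 lower of 19 tested, 7 higher and 6 lower with library sizes alone, and 0 higher and 16 lower on the leukocyte scale. PLK3 (1.33 ± 0.048) and CDKN1A (1.33 ± 0.050) were higher but did not pass on the leukocyte scale, and BTG2 (0.83 ± 0.042) was at -0.44 there. Their test (camera adjusted p = 0.0554) passed without KD replicate 1 (adjusted p = 0.0432) and without KD replicate 2 (adjusted p = 0.0430). Immediate-early genes had 16 higher and 3 lower of 22 tested (camera adjusted p = 0.00124, adjusted p = 0.0635 with an estimated correlation) and 1 higher and 16 lower on the leukocyte scale. IER3 (1.27 ± 0.050) and FOSL1 (1.07 ± 0.047) changed sign between the scales. In these libraries LIN28B was at 86.4 CPM in NC and 0 in KD.

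Genes of RNA modification and translation were lower as groups or divided. The unfolded protein response was mostly higher on the scale of all genes. The m7G methyltransferases and cofactors had 1 higher and 3 lower of 8 tested (camera adjusted p = 0.370), 0 higher and 7 lower with library sizes alone, and all 8 were lower on the leukocyte scale. BUD23 (-1.15 ± 0.047) and CMTR1 (-0.32 ± 0.048) fell beside WDR4. BUD23 is the m7G methyltransferase of 18S rRNA. The m6A and other modification enzymes had 5 higher and 15 lower of 21 tested (camera adjusted p = 0.0398, adjusted p = 0.162 with an estimated correlation) and 0 higher and 21 lower on the leukocyte scale. DKC1, the pseudouridine synthase, fell from 485 ± 15.7 to 239 ± 9.29 CPM and NAT10 (-0.76 ± 0.041) fell, while WTAP (0.97 ± 0.041) was at -0.30 on the leukocyte scale. Cytosolic ribosomal proteins had 3 higher and 54 lower of 57 tested (camera adjusted p = 5.39e-11, adjusted p = 0.0950 with an estimated correlation). RPS4X (-1.92 ± 0.044), RPS2 (-1.33 ± 0.043) and RPL24 (-1.06 ± 0.040) fell, though these genes can share reads with pseudogenes. Aminoacyl-tRNA synthetases had 4 higher and 12 lower of 20 tested (camera adjusted p = 0.178, and adjusted p = 0.0233 with library sizes alone) and 0 higher and 20 lower on the leukocyte scale. FARSB (-1.25 ± 0.064), YARS1 (-0.96 ± 0.040) and IARS1 (-0.61 ± 0.040) fell. ATF4 targets of the integrated stress response had 8 higher and 13 lower of 23 tested (camera adjusted p = 0.171) and 0 higher and 21 lower on the leukocyte scale. Asparagine synthetase (ASNS) fell from 98.8 ± 2.54 to 11.5 ± 0.870 CPM, and the serine synthesis genes PSAT1 (-1.93 ± 0.056) and PHGDH (365 ± 10.4 CPM in NC and 91.2 ± 3.21 CPM in KD) fell. The unfolded protein response had 12 higher and 3 lower of 18 tested (camera adjusted p = 0.00955, adjusted p = 0.0915 with an estimated correlation) and 0 higher and 18 lower on the leukocyte scale. DNAJC3 (1.03 ± 0.042) and SEL1L (0.82 ± 0.041) changed sign, and PDIA4 (-0.59 ± 0.039) was lower on both scales. Heat shock genes had 7 higher and 4 lower of 14 tested (camera adjusted p = 0.178), 6 higher and 6 lower with library sizes alone and 0 higher and 14 lower on the leukocyte scale. BAG3 (0.83 ± 0.040), HSPA8 (0.78 ± 0.045) and HSPH1 (0.75 ± 0.041) were below 0 on that scale. IRS4 was at 164 ± 2.42 CPM in NC and 0.169 ± 0.0770 CPM in KD. The falls in these lists cannot be told apart from RNA of other cells in NC.

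Nuclear-encoded metabolic lists were mostly higher on the scale of all genes and mostly lower on the leukocyte scale. On the latter their members shared the direction of most tested genes, whose median was -1.32. The list medians lay above it, at -0.65 for glycolysis and -1.01 for oxidative phosphorylation. Glycolysis had 18 higher and 3 lower of 21 tested (camera adjusted p = 9.54e-05, adjusted p = 0.0541 with an estimated correlation) and 1 higher and 18 lower on the leukocyte scale. The glucose transporter SLC2A1 (1.47 ± 0.050) rose, HK2 (1.00 ± 0.040) was at -0.28 on the leukocyte scale, and the muscle-type phosphofructokinase PFKM (-2.74 ± 0.076) fell. Hypoxia targets had 13 higher and 1 lower of 16 tested (camera adjusted p = 4.72e-05, adjusted p = 0.0541 with an estimated correlation) and 1 higher and 14 lower on the leukocyte scale. They include SLC2A1 and HK2, and BNIP3L (1.06 ± 0.042) was at -0.22 on that scale. Nuclear-encoded oxidative phosphorylation genes had 27 higher and 5 lower of 39 tested, or 27 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.125 with an estimated correlation). They had 17 higher and 10 lower with library sizes alone and 0 higher and 38 lower on the leukocyte scale. Their examples NDUFB9 (1.21 ± 0.040), NDUFV2 (0.81 ± 0.049) and ATP5F1A (0.62 ± 0.041) changed sign. Mitochondrially encoded mRNAs were all lower, 13 of 13 (camera adjusted p = 5.26e-05, adjusted p = 0.124 with an estimated correlation), with MT-CO3 (-0.78 ± 0.048), MT-ND5 (-0.73 ± 0.049) and MT-CYB (-0.60 ± 0.042). They made up 4.37 ± 0.048% of the counts in NC and 2.74 ± 0.073% in KD (n = 3 each, exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). Cholesterol synthesis genes had 17 higher and 3 lower of 23 tested (camera adjusted p = 2.46e-04, adjusted p = 0.0635 with an estimated correlation) and 2 higher and 21 lower on the leukocyte scale. Squalene epoxidase (SQLE) rose from 452 ± 1.48 to 1247 ± 3.64 CPM, and STARD4 (1.58 ± 0.043) rose. LXR and PPAR targets had 15 higher and 2 lower of 18 tested (camera adjusted p = 1.61e-05, adjusted p = 0.0635 with an estimated correlation) and 5 higher and 11 lower on the leukocyte scale. FABP4 (2.09 ± 0.043) and ABCA1 (1.44 ± 0.039) rose on both scales. NRF2 targets had 14 higher and 1 lower of 17 tested (camera adjusted p = 2.73e-05, adjusted p = 0.124 with an estimated correlation) and 0 higher and 15 lower on the leukocyte scale. GCLC (1.20 ± 0.040), FTH1 (1.18 ± 0.048) and FTL (1.03 ± 0.043) were below 0 on that scale. BEX2 was at 161 ± 6.33 CPM in NC and 0.339 ± 0.0295 CPM in KD.

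**Figure D3:**
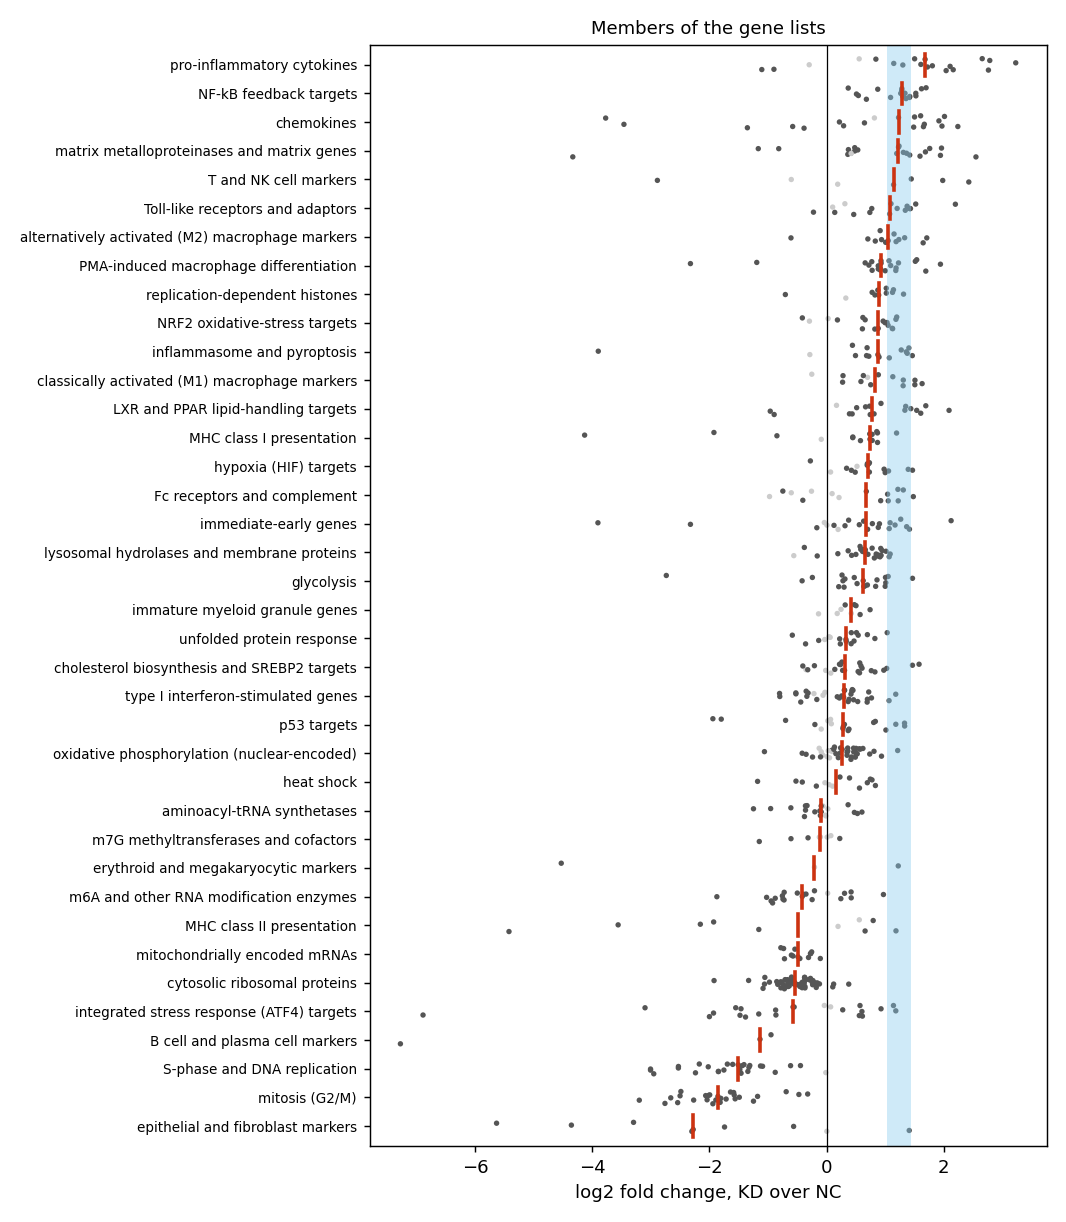
Log2 fold change, KD over NC, of the tested members of the 38 gene lists on the scale of all genes. Each point is a gene, dark where its adjusted p was under 0.05, and each red bar is the list's median. The blue band spans 1.03 to 1.44, the quartiles of the 58 leukocyte-restricted genes. Lists to the left of it include S-phase and mitosis genes. Many lists right of 0 lie at or below the band. Their members were mostly lower on the leukocyte scale, as were most tested genes.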

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

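The scaling with the leukocyte-restricted genes set equal, counts divided by 2 and genes averaging fewer than 10 counts in KD left out were chosen after the data were seen. Under the alternatives chosen before the data were examined, the counts of changed genes stayed within 1.5 times of the values reported, from 14005 with a mean of at least 1 CPM to 17797 with no filter, and 15166 passed at an adjusted p of 0.01. METTL1 kept its sign throughout. It passed with library sizes alone (-0.29, adjusted p = 0.00249), with the leukocyte-restricted genes set equal (-1.38, adjusted p = 8.87e-15) and with genes averaging fewer than 10 counts in KD left out (-0.18, adjusted p = 0.0382), while adjusted p under the others ran up to 0.570. With the leukocyte-restricted genes set equal, 590 genes were higher and 18636 lower, and 13922 changed at least 2-fold, 96 higher and 13826 lower. These shifts follow from the scaling itself, which moves the median of all genes to -1.32. Under it these genes reversed (log2 fold change): WTAP -0.30, SAMD9L -0.095, IRF9 -0.21, CASP4 -0.001, IRAK3 -0.070, GBP2 -0.15, MSR1 -0.041, TGM2 -0.12, LYZ -0.77, CTSG -0.53, RNASE2 -0.70, CD74 -0.090, HLA-DRB1 -0.48, PSMB8 -0.080, C3 -0.23, FCER1G -0.22, C5AR1 -0.052, MAN2B1 -0.21, PSAP -0.26, CTSH -0.19, HK2 -0.28, NDUFB9 -0.061, NDUFV2 -0.47, ATP5F1A -0.66, DNAJC3 -0.24, SEL1L -0.45, BAG3 -0.44, HSPH1 -0.53, HSPA8 -0.50, GCLC -0.078, FTH1 -0.091, FTL -0.24, BNIP3L -0.22, BTG2 -0.44, H2AC6 -0.13, H2BC12 -0.39, H2BC21 -0.15, IER3 -0.009, FOSL1 -0.21 and PPBP -0.047. Of these, CASP4, IRAK3, MSR1, CD74, PSMB8, C5AR1 and NDUFB9 did not pass an adjusted p of 0.05 on that scale. The same held for GCLC, FTH1, H2AC6, H2BC21, IER3 and PPBP, so that for these genes only the sign of the estimate changed. FCER1G is itself among the genes that set the scale. EPOR reversed without KD replicate 1 (0.081), with a range of -0.37 to 0.081 over the single libraries left out. The cause of the EPOR reversal was not tested. With library sizes alone, higher and lower members of lists changed by over 1.5 times for m7G methyltransferases (0 and 7), M1 markers (10 and 1), immature granule genes (3 and 1), oxidative phosphorylation (17 and 10), cholesterol biosynthesis (12 and 5) and cytosolic ribosomal proteins (1 and 54). The same held for the unfolded protein response (9 and 5), NRF2 targets (12 and 2), hypoxia targets (11 and 2) and p53 targets (7 and 6). Under the other alternatives chosen before the data were examined such changes were of 1 or 2 genes, except for lower MHC class II genes, 5 as reported and 1 with a mean of at least 1 CPM. Of the 36 list tests, 28 passed, and 2 did with an estimated correlation, NF-kB feedback targets and S-phase genes. Fry called 36, but it does not compare a list with other genes. Correlations of deviations for equal replicate numbers were 0.12, 0.04 and -0.24, which gives no sign that the numbers pair the samples. Deviations within so few libraries depend on each other, so these values cannot exclude a pairing. With the replicate block 16428 genes changed, and 27 list tests passed, without the interferon list (adjusted p = 0.0529). Depth limits genes with few counts, since low counts were mostly even and so hold fewer independent fragments: with counts divided by 2, 15815 genes changed.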

Other observations

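The tests in this part were chosen after the results were seen, except the count of library splits. Gene families named by symbol were compared with all tested protein-coding genes (Fisher's exact test, adjusted over 30 tests). HOX genes, which set position along the body axis, were at least 2-fold lower in KD in 31 of 34 tested (22.4% of the background, adjusted p = 2.73e-16), and HOXB9 stood at 29.7 ± 1.31 CPM in NC and 0.0679 ± 0.0296 CPM in KD. HOXA9, HOXA10 and HOXA11, chosen after their values were seen, differed least, HOXA9 with 9.11 ± 0.327 CPM in NC and 5.01 ± 0.391 CPM in KD. Kinesins, motor proteins many of which act in mitosis, were at least 2-fold lower in 20 of 34 (adjusted p = 3.58e-05), and semaphorins, ephrins and their receptors in 24 of 48 (adjusted p = 0.000111). Interleukins and their receptors were at least 2-fold higher in 21 of 45 (11.6% of the background, adjusted p = 4.53e-08), integrins in 12 of 28 (adjusted p = 0.000111) and leukocyte immunoglobulin-like and sialic acid-binding receptors in 9 of 15 (adjusted p = 5.69e-05). Collagen chains went both ways, with 12 of 38 at least 2-fold higher (adjusted p = 0.00251) and 13 at least 2-fold lower (adjusted p = 0.232). ZNF genes were at least 2-fold higher less often than the background, in 26 of 450 (adjusted p = 0.000113). These directions are on the scale of all genes, and the higher families were not tested on the leukocyte scale. Of HOX genes, collagens and protocadherins, 1 family was over-represented among the genes at least 2-fold lower. Clustered protocadherins were at least 2-fold higher in 41 of 43, but 7 of 14 PCDHA genes held one identical set of 6 counts, so reads of exons shared within the cluster were counted for each gene and the members are not independent. Keratins, MAGE genes, solute carriers, WNT and frizzled genes, TNF superfamily and RAB genes passed in neither direction.

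The NC libraries held many abundant genes that were near 0 in KD. The CPM given for them here are scaled by library size alone. A response of THP-1 cells alone would leave CDKN2A, which this line is known to lack, and its neighbours CDKN2B and MTAP on chromosome 9 near 0, but the lowest of these in any NC library was 8.40 CPM, and CDKN2A was at 38.6 ± 1.65 CPM in NC and 0.104 ± 0.0906 CPM in KD. NEFM, IRS4 and LIN28B reached at most 0.385 CPM in any KD library. These genes were named under a rule that asked for no overlap between the groups, so they cannot test a swap of single libraries. The splits of the libraries given below argue against such a swap, since the highest number of changed genes in any split but the real one was 0. RNA of another line in the NC libraries would dilute leukocyte genes together, and 96.6% of the leukocyte-restricted genes were higher in KD, with a median log2 fold change of 1.27 (quartiles 1.03 and 1.44), which is consistent with that hypothesis. On library sizes alone the median of 1.09 would correspond to 52.9% of the NC RNA from other cells (44.3% to 57.9% at the quartiles). This share assumes that these genes did not differ between the THP-1 cells of the groups. It also assumes that other cells held none of their RNA and that the KD libraries held THP-1 RNA only. The quartiles give the spread between genes, not the error of the share. Of 19 genes listed for cells of the type of HEK293, an embryonic kidney line, 5 of which had been seen in these data, 18 were at 1 CPM or more in NC and 8 in KD, with 13 lower and 4 higher, and of the most abundant in NC, NEFM was at 1700 CPM in NC and 0.365 CPM in KD and IRS4 at 175 CPM in NC and 0.159 CPM in KD. MAP1B, at 217 CPM in NC and 204 CPM in KD, did not pass on the scale of all genes and was at -1.18 on the leukocyte scale.

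Without the 5 genes seen beforehand, 8 of 14 were lower and 4 higher. Sympathetic neuroblast genes had 4 lower of 4 tested, pluripotent genes 1 of 1, basal epithelial genes 3 lower and 1 higher of 4, fibroblast genes 1 lower and 2 higher of 3, endothelial genes 5 higher of 6 and hepatocyte genes 1 higher of 2. The line is thus not named by these lists.

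Cytokines and chemokines were compared with the 58 leukocyte-restricted genes, since dilution of THP-1 RNA alone would leave them no higher than these. Of the pro-inflammatory cytokines 11 were higher and 4 lower of 19 once leukocyte-restricted genes are set equal, with a median of 0.406, against 20 higher and 19 lower of the 58 leukocyte-restricted genes themselves. The log2 fold changes of the 19 lay 0.425 above those of the leukocyte-restricted genes (95% interval 0.061 to 0.768, Wilcoxon rank sum, adjusted p = 0.0551), which missed the threshold. With a floor of 5 CPM on both sets the shift was 0.469 over 9 cytokines (0.199 to 0.933, adjusted p = 0.00286), and 4 of the 9 lay above each leukocyte-restricted gene and 0 below each. Without a floor 6 of the 19 lay above each leukocyte-restricted gene, of which the highest was 2.10, and 3 lay below each of them. Chemokines had 9 higher and 8 lower of 19 once leukocyte-restricted genes are set equal, with a median of -0.046, and their shift was -0.089 (-0.833 to 0.300, adjusted p = 0.763). With the floor it was 0.233 over 14 genes (-0.146 to 0.515, adjusted p = 0.144). For both lists, dilution as the whole cause and a response that differs between the cells of the groups cannot be told apart, because the test of all cytokines missed the threshold while that with the floor passed, and the interval for chemokines holds shifts in both directions. These tests treat genes as independent.

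S-phase and mitosis genes were lower in KD, with a median of -3.01 once leukocyte-restricted genes are set equal. Cycling cells of another line in NC and a slower cycle of the THP-1 cells labelled KD cannot be told apart, because the level of these genes in the THP-1 part of the NC libraries is not known. For the MHC class II list the median there was -1.75, and a change within the THP-1 cells could not be told apart from MHC class II transcripts of other cells for the same reason. The level of METTL1 and WDR4 in the THP-1 part of the NC libraries is not known either, so the log2 fold changes of METTL1, -0.11 on the scale of all genes and -1.38 on the leukocyte scale, do not show whether METTL1 mRNA was lowered within THP-1 cells.

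The number of changed genes, 16758, was reached by 1 of the 10 splits of the 6 libraries into groups of 3, the real one. The highest of the other splits was 0 with edgeR and with limma-voom, and 61 genes at an unadjusted p under 0.05. With 10 splits no share under 0.05 is possible.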
